A study of Rattus norvegicus with 4 samples.

How the data were processed

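Whole rat ovaries (Rattus norvegicus) of postnatal day 4 were cultured for 10 days without treatment or with 50 ng/mL AMH, each RNA sample came from a pool of about 10 ovaries of 1 group, and 2 pools per group were hybridised as biotin-labelled RNA to 1-colour Affymetrix arrays, per the labels' protocols. The pools are described there as independent, so that the spread between replicates covers culture, extraction and array together. The values used are probe set intensities on a linear scale as deposited by the authors, 1 table of 31099 probe sets by 4 arrays. The software that summarised the probes is not given in the sources used here. On every array the mean without the lowest and highest 2 percent of probe sets was 125.03, so the deposited intensities had been scaled per array to one target, which sets the average change between arrays to near 0. Median intensities were 46.6 and 47.1 on the control arrays and 45.3 and 40.3 on the AMH arrays. The table holds no detection calls, so brightness stood in for them, and read depth does not apply to arrays.

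Groups and replicate numbers came from the sample titles. Values were taken as deposited and turned into log2(intensity + 16), a scale that understates the change of dim probe sets. The 57 Affymetrix control probe sets and the lowest 40 percent of the other probe sets by mean over the 4 arrays (a mean log2 below 5.45, intensity about 27.8) were left out, which left 18625 probe sets. AMH was compared with control in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The fit had 2 residual degrees of freedom and 6.33 prior degrees of freedom from the pooled spread of all probe sets. With 2 arrays per group no permutation of the arrays can reach a small p, so all p-values rest on this pooled model.

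Genes were named from the platform annotation, in which 20832 probe sets have 1 symbol, 436 have several and 9831 have none listed; only the first kind was named. Of these, 20764 matched a gene in a RefSeq table of the GRCr8 assembly by Entrez identifier, all 20764 under the same symbol. Of the tested probe sets, 4584 did not carry exactly 1 symbol (295 of them higher and 378 lower). A gene was represented by its tested probe set with the highest mean over all 4 arrays, and other probe sets of a gene named in the comparisons are given beside it where their sign or call differed. The array's own genome build is not given in the sources used here, so no coordinates are printed, and gene span from the RefSeq table was used only as a property of a gene.

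Before the data were examined, 25 gene lists were fixed: AMH and BMP receptor signalling, TGF-beta family members, oocyte, granulosa and theca markers, regulators of primordial follicle activation, cell cycle, CDK inhibitors and growth arrest, extracellular matrix, apoptosis, cholesterol synthesis, hypoxia and glycolysis, immediate early and heat shock genes, interferon response, Wnt, Notch and gap junction signalling, ribosomal proteins, mitochondrial respiration, and markers of macrophages and leukocytes, endothelium, surface epithelium and mesothelium, smooth muscle and pericytes, red blood cells, adipocytes, and oviduct and ciliated epithelium. Lists share members, such as Gdf9, Bmp15, Kit, Wnt4 and Amhr2. Lists with at least 5 measured genes (24 of 25) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. With an estimated correlation camera works with the fit's 2 residual degrees of freedom, so it had little power here. Members were counted as changed by their adjusted p over all probe sets and, separately, adjusted over the list alone.

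The rule for named genes was also fixed beforehand. It takes the 12 largest rises and the 12 largest falls by log2 fold change among genes past the threshold whose groups do not overlap, for every list the 2 members highest and the 2 lowest by moderated statistic, and a set of genes always named where measured (Amh, its receptors and SMADs, the Id genes, ligands and markers of the follicle, steroidogenic genes and Mki67). Symbols made of LOC or RGD and digits were passed over. Of the always named genes, Cyp17a1 and Fgf2 (16.45 in control and 27.8 with AMH) were below the filter, and Bmpr1b, Figla, Nobox, Fshr and Ctgf had no probe set listed under that symbol (Ccn2, the current symbol of Ctgf, was measured). Some list members are named outside this rule, mostly to complete a short count of changed genes. They were chosen after their values were seen, namely Bmp4, Bmper, Acvr2a, Sycp3, Bcl2l10, Sohlh1, Ooep, Zp2, Isg15, Mx1, Mx2, Irf7, Psmb9, Oas1a, Col1a2, Col6a2, Sparc, Rps9, Rpl3, Rpl7, Ndufb8, Ndufb5, Slc2a1, Slc2a3, Pfkfb3, Nr4a1, Jund, Cdkn1c, Cdkn1b, Rb1, Igf1, Pdpk1, Fzd1, Lrp6, Cdh1, Hsd3b1, Bub1b, Mcm2 and Ccn2.

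The fit was tested on simulated data for the comparison of AMH with control over 18625 probe sets, drawn from the real means and spread. It recovered 0 of 65 probe sets changed 1.5-fold, 9 of 59 (15.3%) changed 2-fold and 47 of 57 (82.5%) changed 4-fold, all with the right sign, made 2 false calls among 58, and made 0 calls in data without any change. Far fewer probe sets were changed there than the 3999 that passed in the real comparison. The adjusted threshold was thus stricter in the simulation, and its recovery rates do not carry over. In simulated lists the 1 shifted list was called and 0 of the others, with noise drawn independently for each probe set and camera at the preset correlation. False list calls among correlated genes were therefore not assessed.

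Alternatives fixed beforehand were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter of the lowest 60 percent, eBayes without trend and robust, the replicate number as a block, other thresholds, a fold rule of 1.5 without a test, leaving out _x_at probe sets, averaging the probe sets of a gene, other list tests and leaving out each array in turn. Scaling to the hybridization control probe sets and removing a trend with gene span were added after the data had been seen.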

Results

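Gene expression was measured in rat ovaries taken on postnatal day 4, when most follicles are primordial, and kept as whole organs in culture for 10 days. The ovaries were cultured either without added hormone (control) or with 50 ng/mL anti-Müllerian hormone (AMH), a member of the TGF-beta family that granulosa cells of growing follicles secrete. The question, from the series title, was which transcripts change when AMH holds back the step from primordial to primary follicle. RNA from about 10 ovaries was pooled for each sample, 2 independent pools were made per group, and each pool was hybridised to 1 Affymetrix array, so that 4 arrays were compared. The table held 31099 probe sets, of which 18625 were bright enough to be tested. Changes are given as AMH minus control on the log2(intensity + 16) scale, ± the standard error of the limma fit (n = 2 arrays per group), and the number of arrays limits their precision.

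The arrays separated by group. Over the tested probe sets the correlation across probe sets was 0.974 between the control arrays and 0.955 between the AMH arrays, against 0.877 to 0.902 between arrays of different groups. The 3′/5′ intensity ratio of the GAPDH control probe sets, which increases when RNA or its labelled copy is shortened, was 1.17 and 1.27 on the control arrays and 6.56 and 6.37 on the AMH arrays. For beta-actin it was 3.17 and 4.6 on the control arrays and 10.7 and 14.4 on the AMH arrays. The 9 hybridization control probe sets, which report material added after RNA extraction, had geometric means of 947.6 and 1044 on the control arrays and 1530 and 1266 on the AMH arrays. The chip identifiers carried 2 run strings, 0 of them shared by both groups, so batch and group cannot be told apart in any result that follows.

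**Figure D1:**
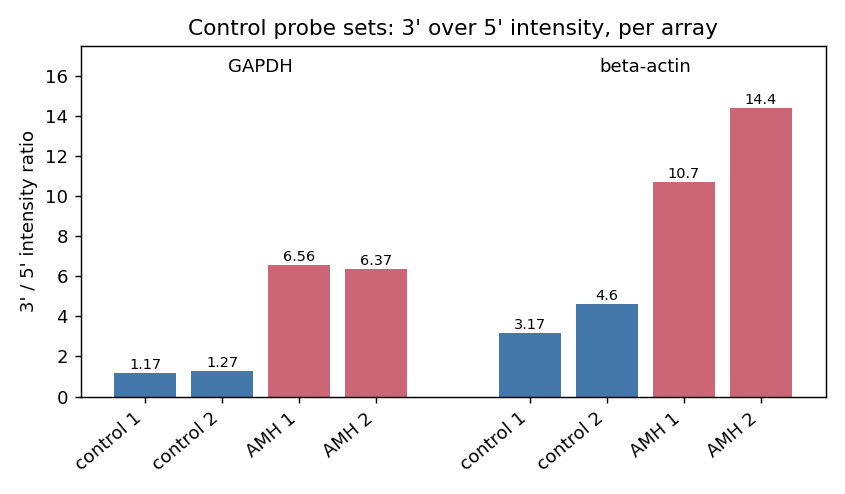
Ratio of 3′ to 5′ intensity (vertical axis, no unit, from 0) of the GAPDH and beta-actin control probe sets on each array, 1 bar per array, control in blue and AMH in red. The GAPDH ratio lies at 1.17 and 1.27 on the control arrays and at 6.56 and 6.37 on the AMH arrays.

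With each gene taken at its brightest probe set, the largest rise with AMH was that of Ptgs2, the inducible prostaglandin synthase, at 2.26 ± 0.39 (4.8-fold; intensity 61.1 ± 21.78 to 384.4 ± 239.4, mean ± SD, adjusted p = 0.00664). On the same basis Hbb, haemoglobin beta, fell furthest, by 3.88 ± 0.22 (14.7-fold, adjusted p = 0.000219), Mif, a cytokine, fell by 3.32 ± 0.22 (10-fold, adjusted p = 0.000268) and Rpl24, a ribosomal protein, fell by 2.69 ± 0.18 (6.45-fold, adjusted p = 0.000268). In all, 3999 probe sets (21.5% of those tested) passed an adjusted p of 0.05, 1614 of them higher and 2385 lower with AMH. By gene, 1173 of 10622 were higher and 1259 lower. Falls were also larger than rises: 1341 of the lower probe sets but 334 of the higher ones changed at least 2-fold.

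The split between rises and falls depended on how the arrays were put on a common scale. The deposited values gave 59.6% of the changed probe sets as lower (median change of all tested probe sets 0.025), median centring gave 47.9% (2017 higher and 1858 lower, median change 0.121) and scaling to the hybridization controls gave 97.2% (145 higher and 4960 lower, median change -0.39). Among the 14070 tested probe sets of genes with a known span, removal of a trend with span gave 49.5% (1826 higher and 1787 lower). The count also depended on the array left out: fewer probe sets passed without a control array and more without an AMH array. In such fits the residual spread came only from the group still holding both arrays. The SD of the log2 difference was 0.435 between the AMH arrays and 0.318 between the control arrays. Calls reported below as lost without a control array were therefore judged on the wider AMH spread, and need not reflect that control array. Calls gained or kept without an AMH array rest on the narrower control spread alone. Their p-values, for genes and lists, ignore the spread between the AMH arrays and may be too small.

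Ptgs2 was followed by 11 further genes among the largest rises. Cthrc1, a secreted protein of collagen-rich tissue, rose by 2.17 ± 0.39, Srpx2 by 1.77 ± 0.19, the lysosomal protease gene Ctsc by 1.94 ± 0.24 and the lysosomal membrane gene Scarb2 by 1.83 ± 0.28. Hsd11b1, which regenerates active glucocorticoid, rose by 1.73 ± 0.25, G0s2, an inhibitor of lipolysis, by 1.72 ± 0.23 and Isyna1, which makes inositol phosphate, by 1.88 ± 0.43. The neuropeptide Y receptor gene Npy1r rose by 2.01 ± 0.52 from a control intensity of 15.05 to 136.6. Wnt5a rose by 1.75 ± 0.51 (22.5 and 20.6 in control, 224.9 and 50.5 with AMH), Mrgprf by 1.76 ± 0.38 (2.5 and 15.7 to 94.2 and 45) and Stfa2l2 by 1.71 ± 0.39 (16.9 and 9.9 to 47.6 and 127.6). Control values of these 4 genes lay below the filter level of 27.8, so their log2 values depend on the constant added: with 64 added they were 1.19 for Npy1r, 1.09 for Wnt5a, 0.85 for Mrgprf and 0.92 for Stfa2l2. The AMH arrays lay far apart for several of these: without AMH replicate 1 the log2 fold change was 1.61 for Ptgs2, 1.55 for Cthrc1, 1.06 for Npy1r, 1.05 for Isyna1 and 0.82 for Wnt5a, and without AMH replicate 2 it was 2.92, 2.80, 2.95, 2.71 and 2.68. For Stfa2l2 the values were 2.30 and 1.12. The adjusted p of these genes lay between 0.000914 for Srpx2 and 0.0419 for Wnt5a. Without AMH replicate 1 that of Wnt5a was 0.0609, and without control replicate 1 that of Mrgprf was 0.0533. With no filter on dim probe sets, Npy1r had an adjusted p of 0.0674. A second probe set for Ctsc gave a log2 fold change of 0.25, and the mean over both had an adjusted p of 0.0625. Over all alternatives the adjusted p of these 4 genes ran from 8.28e-05 (Npy1r) to 0.0919 (Wnt5a).

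Besides Hbb, Mif and Rpl24, the 12 largest falls held 9 further genes. Pfdn5, a subunit of the prefoldin chaperone, fell by 3.66 ± 0.38 (12.7-fold, with -3.03 without AMH replicate 1 and -4.29 without AMH replicate 2), Ppif, a mitochondrial prolyl isomerase (-2.94 ± 0.21), Lsm2, an RNA-binding protein (-2.90 ± 0.23), and Atp5mg, an ATP synthase subunit (-2.63 ± 0.18), fell as well. Cxcl6, a neutrophil-attracting chemokine, fell by 3.04 ± 0.24 (intensity 483.6 to 43.65). Uchl1, a deubiquitinating enzyme abundant in germ cells and neurons, fell by 2.87 ± 0.18, and so did Akirin2 (-2.62 ± 0.26, intensity 209 to 20.95, and -1.68 with 64 added, as its AMH level was below that of the filter) and S100a11 (-2.61 ± 0.20). Col1a1, which encodes a chain of type I collagen, fell 7.98-fold at its brighter probe set (-2.996 ± 0.272), while the other probe set gave -0.54 ± 0.23 and did not pass (adjusted p = 0.13). The adjusted p of these 12 falls lay between 0.000219 and 0.000817, and each passed under every alternative in which it was tested. No alternative addressed the 3′/5′ ratio or the batch, which both differed between the groups. Control probe sets fell on the same arrays and scale. Beta-actin gave -3.82 at its 5′ and -2.36 at its 3′ end, and GAPDH -2.68 and -0.32.

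**Figure D2:**
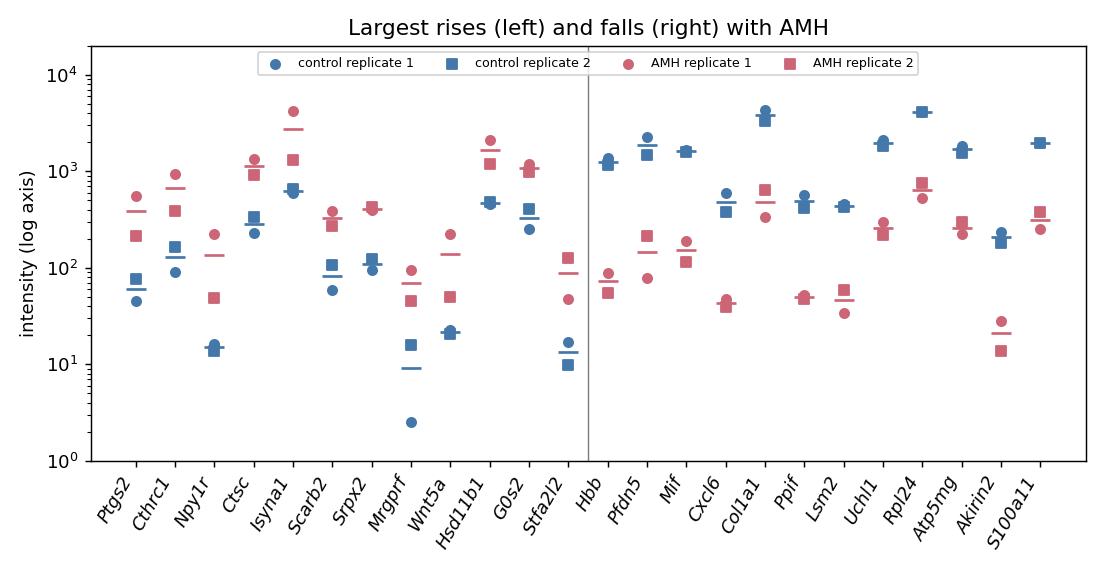
Intensity on each array (vertical axis, log scale) of the 12 largest rises (left) and the 12 largest falls (right) among genes whose groups did not overlap, with circles for replicate 1, squares for replicate 2, control in blue, AMH in red and a short line at each group mean. For Hbb the control arrays read 1362 and 1166.8 and the AMH arrays 89.4 and 55.3.

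Genes of the pathway that AMH itself uses moved in both directions. A larger share of them was called than of all tested genes (1173 of 10622 higher and 1259 lower). Of 18 measured genes of AMH and BMP receptor signalling, 3 were higher, 4 lower and 11 not called (3 and 4 adjusted over the list alone, and 0 and 5 with hybridization control scaling). Id3 and Id1, transcriptional targets of BMP signalling, fell by 1.58 ± 0.18 (adjusted p = 0.00128) and 0.95 ± 0.16 (adjusted p = 0.00551). Bambi, a decoy receptor that BMP signalling induces, fell by 1.41 ± 0.19 (adjusted p = 0.0027) and Bmpr2, a type II receptor, by 1.07 ± 0.21 (adjusted p = 0.0102). Amhr2, the AMH receptor, rose by 0.70 ± 0.21 (adjusted p = 0.0462), Smad9 by 0.71 ± 0.19 (adjusted p = 0.0341) and one probe set of the ubiquitin ligase gene Smurf2 by 0.69 ± 0.20 (adjusted p = 0.0448), while its other probe set was lower (-0.72, adjusted p = 0.0474). Amh itself (0.42 ± 0.18), Bmpr1a (-0.19 ± 0.20), Acvr1 (0.43 ± 0.18), Smad1 (0.10 ± 0.16), Smad5 (-0.19 ± 0.19) and Id2 (-0.07 ± 0.18) were not called at their brightest probe sets. Dimmer probe sets of 4 of these genes were called lower: Acvr1 at -0.92 (adjusted p = 0.0163) and -1.31 (0.0151), Smad1 at -1.14 (0.0249), Smad5 at -1.92 (0.00183) and -0.83 (0.0473), with a further one at 0.22 (0.443), and Id2 at -2.89 (0.00142). The AMH means behind -1.31 (13.05), -1.14 (15.55), -1.92 (17.9) and -2.89 (24.95) lay below the filter level of 27.8. The size of these falls therefore depends on the constant added. With the gene span trend removed Amh passed (0.67, adjusted p = 0.0285), and the means over probe sets passed for Id2 (-1.48, adjusted p = 0.00415) and Smad5 (-0.68, adjusted p = 0.0269). The list did not shift as a whole (limma camera, adjusted p = 0.794), and its median (0.01), its mean (-0.11) and the direction of the test (down) differed in sign. Leaving out control replicate 1 ended the calls of Id1 (0.0646), Smad9 (0.149) and Smurf2 (0.331), and leaving out control replicate 2 those of Bmpr2 (0.0781), Amhr2 (0.324) and Smad9 (0.183). Smad9 (0.0713) and Smurf2 (0.0851) were also lost without AMH replicate 1 and Amhr2 (0.0861) without AMH replicate 2. Over all alternatives the adjusted p of these 5 genes ran from 0.00172 (Id1) to 0.97 (Smurf2). The rise of Smurf2 was lost in 8 of 15 alternatives and that of Amhr2 in 9, among them quantile normalization (0.0635), median centring (0.0504) and hybridization control scaling (0.604).

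Within the wider TGF-beta family, the activin subunit genes Inhbb and Inhba rose and the oocyte-derived ligand genes Gdf9 and Bmp15 fell. Inhbb rose by 1.51 ± 0.29 (adjusted p = 0.01, AMH arrays 1473.9 and 707.5, 0.99 without AMH replicate 1 and 2.03 without AMH replicate 2) and Inhba by 1.27 ± 0.29 (adjusted p = 0.0181). The activin receptor gene Acvr2a rose by 0.90 ± 0.23. The BMP-binding gene Bmper rose by 1.43 ± 0.43 (0.785 without control replicate 1 and 1.011 without AMH replicate 2). Gdf9 fell by 2.14 ± 0.18 (intensity 1729 to 385.7, adjusted p = 0.00051), Bmp15 by 1.93 ± 0.23 (131.4 to 22.45, below the filter level of 27.8, adjusted p = 0.00155, and -1.17 with 64 added) and Bmp4, made by stromal cells, by 1.06 ± 0.22 (adjusted p = 0.0128). Of the 24 measured members, 4 were higher, 3 lower and 17 not called (4 and 4 adjusted over the list alone). With hybridization control scaling the count was 1 higher and 8 lower, and the call of Inhba was lost (0.0697). Inha gave 1.07 ± 0.45 with widely different AMH arrays (1930.6 and 566.2) and was not called (1.94 without AMH replicate 2). Tgfb1 (-0.08 ± 0.23) and Tgfb2 (-0.44 ± 0.18, with another probe set called at -1.73, adjusted p = 0.0095) were not called. Tgfb2 passed in the mean of its probe sets (-1.08, adjusted p = 0.0139) and with hybridization control scaling (0.0146). The list as a whole did not shift (adjusted p = 0.794), with a median of 0.04, a mean of -0.02 and a downward test. The calls of Bmper (0.208) and Acvr2a (0.129) ended without control replicate 1, those of Inhba (0.0556), Bmp4 (0.121) and Acvr2a (0.0913) without control replicate 2, that of Acvr2a (0.064) without AMH replicate 1 and that of Bmper (0.118) without AMH replicate 2. Bmper failed in 9 of 15 alternatives, median centring (0.0521) and no filter (0.0984) among them. Over all alternatives the adjusted p of these 4 genes ran from 0.00085 (Inhba) to 0.208 (Bmper).

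Oocyte markers fell as a list, but not all of its members moved. Of 11 measured markers 7 were lower, 1 higher and 3 not called (7 and 1 adjusted over the list alone), with a median of -1.01 and a camera adjusted p of 0.00437. The call was lost when the correlation between genes was estimated (adjusted p = 0.984 with an estimated correlation). Beside Gdf9 and Bmp15, the transcription factor gene Sohlh1 fell by 1.86 ± 0.28, Bcl2l10 by 1.15 ± 0.24 and the meiotic gene Sycp3 by 1.01 ± 0.24. The receptor gene Kit also fell, from 75 and 45 in control to 18.9 and 3.9 with AMH. Its AMH values lie below the filter level of 27.8, so the size of this fall depends on the constant added (-1.499 ± 0.352 with 16 and -0.71 with 64). The zona pellucida genes Zp2 (0.00 ± 0.17) and Zp3 (0.00 ± 0.18, intensity 2332 ± 281.1 to 2350 ± 526.1) did not differ by more than the arrays of a group did, and the connexin gene Gja4 rose by 0.70 ± 0.18. Ooep fell by 0.61 ± 0.17, a call lost in 8 of 15 alternatives. With the lowest 60% of probe sets left out the adjusted p of the list was 0.0742 (0.00108 to 0.984 over 17 alternatives). The calls of Kit (0.131), Sycp3 (0.118), Ooep (0.291) and Gja4 (0.194) were lost without control replicate 1, and those of Bcl2l10 (0.103), Ooep (0.0815) and Gja4 (0.0787) without control replicate 2 (over all alternatives, 0.00125 for Sycp3 to 0.56 for Gja4). On the same arrays the mean GAPDH 3′/5′ ratio was 1.22 in control and 6.46 with AMH.

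Granulosa cell markers were called about as often as all tested genes (1173 of 10622 higher and 1259 lower). Of 23 measured, 4 rose (Inhbb, Inhba, Wnt4 and Amhr2) and 2 fell (5 and 2 adjusted over the list alone), and 17 were not called. With hybridization control scaling 1 rose and 3 fell, and the calls of Wnt4 (0.415), Amhr2 (0.604) and Inhba (0.0697) were lost. Foxo1 fell by 2.30 ± 0.23 (intensity 210.2 to 30.2, adjusted p = 0.000708) and Gata4 by 0.90 ± 0.18 (adjusted p = 0.0122, with -0.25 at another probe set). Wnt4, which directs ovarian differentiation, rose by 0.74 ± 0.16. Foxl2 (0.39 ± 0.18), Kitlg (0.38 ± 0.26) and Cyp19a1 (0.18 ± 0.31, near the floor at 25.4 and 31.9) were not called, though Kitlg passed without AMH replicate 1 (0.75, adjusted p = 0.0255) and Foxl2 with the gene span trend removed (0.61, adjusted p = 0.0402). For Inhbb the AMH arrays differed, with 0.99 left without AMH replicate 1. The list median was 0.39 (-0.05 with hybridization control scaling) and the list did not shift (adjusted p = 0.277). It passed upward without AMH replicate 2 (0.00784) and, relative to the other genes, with hybridization control scaling (0.0456), against 0.59 without AMH replicate 1. The calls of Wnt4 (0.187) and Gata4 (0.123) ended without control replicate 1, those of Amhr2 (0.324) and Inhba (0.0556) without control replicate 2 and that of Amhr2 (0.0861) without AMH replicate 2. The mean over the probe sets of Gata4 had an adjusted p of 0.0955, and over all alternatives these 4 genes ran from 0.00085 (Inhba) to 0.604 (Amhr2).

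Theca and steroidogenic genes gave 2 rises and 1 fall among 10 measured (2 and 1 adjusted over the list alone, but 0 rises and 3 falls with hybridization control scaling). Fdx1, the electron donor of mitochondrial steroid synthesis, rose by 1.06 ± 0.15 (adjusted p = 0.00284) and Aldh1a1 by 0.77 ± 0.21, while Por fell by 0.73 ± 0.22. Star (1.01 ± 0.52) and Hsd3b1 (1.74 ± 0.66) were not called, and their AMH arrays lay far apart (382.9 and 86.5 for Star, 1840.3 and 311.8 for Hsd3b1). Without AMH replicate 2 they gave 1.99 and 2.99, and without AMH replicate 1 0.03 and 0.49. Hsd3b1 gave 2.098 without control replicate 1, and it passed with the replicate number as a block (1.741, limma adjusted p = 0.0142). Scarb1 (-0.44 ± 0.24) was not called at its brighter probe set. Its other probe set was called lower (-1.43, adjusted p = 0.0039), and so was the mean of both (-0.934, adjusted p = 0.0206). Cyp17a1 was too dim to be tested (2.65 in control and 17.75 with AMH). The list did not shift (median 0.51, adjusted p = 0.656) except without AMH replicate 2 (0.0398, against 0.928 without AMH replicate 1). The call of Aldh1a1 was lost without control replicate 1 (0.221) and AMH replicate 2 (0.0673), and that of Por without control replicate 1 (0.174), control replicate 2 (0.187) and AMH replicate 2 (0.0881). Por failed in 8 of 15 alternatives, and Aldh1a1 ran from 0.00289 to 0.474 over its own.

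Among 30 measured regulators of primordial follicle activation, 4 rose and 9 fell (7 and 9 adjusted over the list alone, 0 and 11 with hybridization control scaling, and 0 and 2 without control replicate 1). The falls included Igf1r, the IGF1 receptor (1.71 ± 0.24, adjusted p = 0.00323, with -0.73 at another probe set), Kit, and Eif4ebp1, a brake on translation (0.80 ± 0.16, adjusted p = 0.0124). The rises were Cxcr4 (0.78 ± 0.16), Igf1 (0.71 ± 0.20), Pdgfra (0.67 ± 0.16) and Pdpk1 (0.59 ± 0.18). Other probe sets were called lower for Cxcr4 (-1.12, adjusted p = 0.0106, with 0.52 at another), where the call is lost in the mean of its probe sets (adjusted p = 0.849), and for Igf1 (-0.90, adjusted p = 0.012, with 0.05 at another), whose probe sets averaged -0.05. The list did not shift (median -0.07, adjusted p = 0.794), and Ccn2 (-0.40 ± 0.21) was not called, but passed without AMH replicate 2 (-0.68, adjusted p = 0.0151) and with hybridization control scaling (0.0459). Leaving out control replicate 1 ended the calls of Kit (0.131), Cxcr4 (0.14), Igf1 (0.307), Pdgfra (0.187), Pdpk1 (0.186) and Eif4ebp1 (0.12). Without control replicate 2 those of Pdgfra (0.0696), Pdpk1 (0.218) and Eif4ebp1 (0.0591) were lost, and without AMH replicate 1 that of Pdpk1 (0.0879), which failed in 8 of 15 alternatives. Across all alternatives these 6 genes ran from 0.00167 (Pdgfra) to 0.876 (Igf1).

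Cell cycle genes were called about as often as all tested genes (1173 of 10622 higher and 1259 lower). Of 40 measured, 4 rose, 6 fell and 30 were not called (5 and 6 adjusted over the list alone, 0 and 13 with hybridization control scaling, and 0 and 4 without control replicate 1). Birc5, needed for chromosome segregation, fell by 1.81 ± 0.19 (adjusted p = 0.000914) and Ccnb1, a mitotic cyclin, by 1.08 ± 0.14 (adjusted p = 0.00204) with its other probe set also called (-1.02). Bub1 (0.74 ± 0.16), Cdk1 (0.70 ± 0.15), Bub1b (0.70 ± 0.20) and Mcm2 (0.68 ± 0.16) rose, and the proliferation marker Mki67 (0.58 ± 0.18, adjusted p = 0.0539) was not called, but passed without AMH replicate 1 (0.0377), with median centring (0.0497) and with the gene span trend removed (0.0344). Among 15 growth arrest genes, Ccng2 (0.86 ± 0.17), Rbl1 (0.84 ± 0.21), Cdkn1c (0.68 ± 0.20, and 0.393 without AMH replicate 2) and Rb1 (0.67 ± 0.20) rose, and Gadd45a (-1.80 ± 0.29), Cdkn2c (-1.07 ± 0.16) and Cdkn1b (-0.55 ± 0.17) fell (4 and 4 adjusted over the list alone, 0 and 4 with hybridization control scaling). Among 22 apoptosis genes, Casp8 (0.65 ± 0.20, with -0.44 at another probe set and an adjusted p of 0.716 in their mean) and Mcl1 (0.57 ± 0.14, with another probe set called at -0.73, adjusted p = 0.0356) rose and Bik (-1.06 ± 0.20) and Casp6 (-0.79 ± 0.18) fell (1 and 2 adjusted over the list alone, 0 and 5 with hybridization control scaling). None of these 3 lists shifted (adjusted p = 0.882, 0.981 and 0.998). Their medians (0.09, 0.08 and 0.10) and means (-0.04, -0.03 and -0.01) differed in sign, with tests directed down, up and down. Without control replicate 1 the adjusted p was 0.127 for Bub1, 0.101 for Cdk1, 0.215 for Bub1b, 0.15 for Mcm2, 0.138 for Rbl1 and Cdkn1c, 0.288 for Rb1, 0.201 for Cdkn1b, 0.148 for Casp8, 0.188 for Mcl1, 0.0731 for Bik and 0.109 for Casp6. Without control replicate 2 it was 0.0749 for Bub1, 0.121 for Cdk1, 0.0977 for Bub1b, 0.111 for Mcm2, 0.0893 for Ccng2, 0.0711 for Rbl1, 0.166 for Cdkn1c, 0.146 for Rb1, 0.276 for Cdkn1b, 0.289 for Casp8, 0.174 for Mcl1 and 0.152 for Casp6. Without AMH replicate 1 the calls of Bub1b (0.0739) and Rb1 (0.0786) were lost, and without AMH replicate 2 those of Cdkn1c (0.0732), Cdkn1b (0.0763) and Casp8 (0.0834). Cdkn1c and Cdkn1b each failed in 10 of 15 alternatives and Casp8 in 8. Across all alternatives the adjusted p of these 13 genes ran from 0.00163 (Cdkn1c) to 0.795 (Mcl1).

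Extracellular matrix genes held both rises and falls. Of 47 measured, 14 rose, 7 fell and 26 were not called (16 and 9 adjusted over the list alone). The balance turned over with hybridization control scaling (2 rose and 13 fell) and without control replicate 1 (4 and 5). The crosslinking enzyme gene Loxl1 rose by 1.34 ± 0.15 (adjusted p = 0.00125) and the protease gene Adamts1, which is induced around ovulation, by 1.42 ± 0.24 (adjusted p = 0.00594). Beside the discordant probe sets of Col1a1, Col1a2 fell by 1.27 ± 0.29 (-0.46 at another probe set), Col6a2 by 1.27 ± 0.29, Sparc by 1.32 ± 0.23 and the protease inhibitor gene Timp1 by 0.96 ± 0.15 (adjusted p = 0.00445, and 0.0507 without control replicate 1). The list did not shift (median 0.25, -0.23 with hybridization control scaling, adjusted p = 0.656), and without AMH replicate 1 Col1a2 gave -0.75 and Col6a2 -0.77 (-1.79 and -1.77 without AMH replicate 2). The mean of the probe sets of Col1a2 had an adjusted p of 0.0891 (1.34e-05 to 0.0891 over its alternatives).

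Glycolytic and hypoxia-responsive genes gave 10 rises and 2 falls among 24 measured (1 and 4 with hybridization control scaling), with 10 and 2 also adjusted over the list alone. Without control replicate 1 only 1 rose and 0 fell. Pfkp, a phosphofructokinase, rose by 1.23 ± 0.23 (adjusted p = 0.00821), Pfkfb3 by 1.11 ± 0.23 and Pgam1 by 0.95 ± 0.19 (adjusted p = 0.0104). The glucose transporter genes Slc2a3 and Slc2a1 rose by 1.04 ± 0.31 (0.649 without AMH replicate 2) and 0.84 ± 0.21 (0.552 without control replicate 1). Vegfa, an angiogenic growth factor, rose by 1.02 ± 0.25 at one probe set and gave -0.05 at the other. Tpi1, another glycolytic enzyme gene, fell by 0.77 ± 0.14 and Ddit4, a stress-induced inhibitor of mTOR, by 0.79 ± 0.21 (-0.49 without AMH replicate 2). The list did not pass (median 0.31, -0.16 with hybridization control scaling, adjusted p = 0.306) except without control replicate 2 (0.0128, against 0.567 without control replicate 1). Leaving out control replicate 1 ended the calls of Pfkfb3 (0.106), Pgam1 (0.0704), Slc2a3 (0.224), Slc2a1 (0.229), Vegfa (0.153), Tpi1 (0.0805) and Ddit4 (0.136). Those of Tpi1 (0.064) and Ddit4 (0.0988) ended without control replicate 2 and that of Slc2a3 (0.13) without AMH replicate 2, and across all alternatives these 7 genes ran from 0.000261 (Pgam1) to 0.27 (Slc2a1).

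Among 23 immediate early and heat shock genes, 6 rose and 3 fell (7 and 4 adjusted over the list alone, 1 and 6 with hybridization control scaling, and 1 and 0 without control replicate 1). Fos rose by 1.53 ± 0.25 (adjusted p = 0.00566), the orphan receptor gene Nr4a1 by 1.32 ± 0.36 (0.755 without AMH replicate 1) and Hspa5, the chaperone of the endoplasmic reticulum, by 0.99 ± 0.16 (adjusted p = 0.00534). Zfp36 (-1.19 ± 0.34, and -0.68 without AMH replicate 2), Junb (-0.84 ± 0.25) and Jund (-0.45 ± 0.14) fell. Of 20 cholesterol synthesis genes, Msmo1 (2.3-fold, 1.202 ± 0.172) and Cyp51 (0.68 ± 0.18, with 0.17 at another probe set) rose and Idi1 (-1.73 ± 0.25, with 0.14 at another probe set) fell, as also adjusted over the list alone (1 rise and 4 falls with hybridization control scaling). Neither list shifted (adjusted p = 0.794 and 0.656). Without control replicate 1 the adjusted p was 0.11 for Nr4a1, 0.052 for Hspa5, 0.0555 for Zfp36, 0.137 for Junb, 0.287 for Jund and 0.251 for Cyp51. Without control replicate 2 it was 0.146 for Zfp36, 0.231 for Junb, 0.297 for Jund and 0.0574 for Cyp51. Without AMH replicate 1 the calls of Nr4a1 (0.0805) and Junb (0.0905) were lost, and without AMH replicate 2 that of Zfp36 (0.0705). Zfp36 and Junb each failed in 7 of 14 alternatives. Across all alternatives these 6 genes ran from 0.000476 (Hspa5) to 0.517 (Cyp51).

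Genes of the interferon response were lower as a list with AMH, but only through 1 of the 2 AMH arrays. Of 25 measured, 8 fell, 0 rose and 17 were not called (8 and 0 adjusted over the list alone), with a median of -0.73 and a camera adjusted p of 0.00234. The call was lost in the run with an estimated correlation (0.633 between members, adjusted p = 0.984). Ifitm3, an antiviral membrane protein, fell by 2.39 ± 0.14 (intensity 3529 to 659.1, adjusted p = 0.000268), Psmb9, a subunit of the immunoproteasome, by 1.77 ± 0.28, Oas1a by 1.04 ± 0.18 and the transcription factor gene Irf1 by 0.95 ± 0.15 (adjusted p = 0.00488). Mx2 fell by 1.55 ± 0.44 (adjusted p = 0.0398, AMH arrays 43.5 and 167.3), with -0.74 without AMH replicate 1 and -2.36 without AMH replicate 2. Its call was lost without control replicate 2 (0.0581) and in 3 more of 15 alternatives (7.44e-05 to 0.0825), while its second probe set gave -4.10 (adjusted p = 0.000686), a larger fall than that of Hbb. Isg15 (-0.96 ± 0.76), Mx1 (-0.78 ± 0.73) and Irf7 (0.01 ± 0.60) were not called, and without AMH replicate 1 their log2 fold changes were 0.53, 0.60 and 1.16. Without AMH replicate 2 they were -2.44, -2.15 and -1.14. The adjusted p of Irf7 reached 0.997 over its alternatives. Without AMH replicate 1 the list was no longer called (median 0.01), and without AMH replicate 2 its median was -1. Over 17 alternatives the adjusted p ran from 8.14e-10 to 0.984. The mean GAPDH 3′/5′ ratio on these arrays was 1.22 in control and 6.46 with AMH.

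Ribosomal protein genes were lower as a list, with the lowest adjusted p of any list at the preset correlation. Of 22 measured, 14 fell, 1 rose and 7 were not called (14 and 1 adjusted over the list alone), with a median of -0.60 and a camera adjusted p of 1.59e-07. The call was lost with an estimated correlation (adjusted p = 0.984 with an estimated correlation). Rps24 fell by 2.20 ± 0.15 (intensity 8130 to 1761), Rpl14 by 2.09 ± 0.14 and Rps9 by 2.07 ± 0.16, each with an adjusted p at or below 0.000344, while Rpl22 (0.31 ± 0.13, intensity 5699 to 7082) was not called, but passed without AMH replicate 2 (0.032) and with quantile normalization (0.0198). Rpl28 rose by 0.81 ± 0.25 from 24.05 to 54.3, close to the filter on dim probe sets, and was not called without control replicate 1 (0.168), control replicate 2 (0.26) or AMH replicate 2 (0.0982), with 0.0168 to 0.26 over 14 alternatives, 8 of which ended the call. Rps24 has a dimmer probe set that gave 0.44 ± 0.21. The list kept its call with quantile normalization (median -0.28, adjusted p = 0.000382). With hybridization control scaling the median was -1.08, but that scaling moves all genes of an array nearly alike and so hardly tests the call. Over 17 alternatives its adjusted p ran from 5.42e-10 to 0.984.

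Mitochondrial respiration genes were lower by a smaller margin. Of 27 measured, 10 fell, 3 rose and 14 were not called (11 and 6 adjusted over the list alone), with a median of -0.32 and a camera adjusted p of 0.0488, a call lost with an estimated correlation (adjusted p = 0.984 with an estimated correlation). Ndufb8 and Ndufa5 of complex I fell by 2.29 ± 0.29 (-1.18 with 64 added, as its AMH level of 7.6 is near the floor) and 1.88 ± 0.20, and Sdhb of complex II by 1.38 ± 0.16. Cyc1 (0.78 ± 0.15) and Uqcrc2 (0.66 ± 0.14) of complex III and Ndufb5 (0.81 ± 0.18) rose, but the other probe set of Uqcrc2 was called lower (-1.31, adjusted p = 0.00874). The list passed 0.05 narrowly and was lost without AMH replicate 1 (adjusted p = 0.376), without control replicate 1 (0.0618), with median centring (0.0512) and with the gene span trend removed (0.0985). In all 10 of 17 alternatives ended its call (0.00292 to 0.984). The calls of Cyc1 (0.102), Uqcrc2 (0.187) and Ndufb5 (0.0609) were lost without control replicate 1, and those of Uqcrc2 (0.0613) and Ndufb5 (0.0751) without control replicate 2 (0.000643 for Ndufb5 to 0.573 for Uqcrc2 over all alternatives). Ribosomal and respiratory falls were measured on arrays whose mean beta-actin 3′/5′ ratio was 3.88 in control and 12.6 with AMH.

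Of 19 red blood cell markers only 3 were measured, too few for a list test. Hbb fell by 3.88 ± 0.22 and Hba-a3 by 1.06 ± 0.28 (adjusted p = 0.0313, and 0.108 without control replicate 2), a call lost in 4 of 15 alternatives, with -0.63 without AMH replicate 2 and -1.50 without AMH replicate 1. Alas2 (-0.86 ± 0.31, adjusted p = 0.0839) was not called, but passed without AMH replicate 2 (0.0137) and with hybridization control scaling (0.022), and adjusted over the list alone 3 were lower and 0 higher. The mean GAPDH 3′/5′ ratio beside these falls was 1.22 in control and 6.46 with AMH. Surface epithelium and mesothelium markers gave 3 falls and 1 rise among 15 (4 and 1 adjusted over the list alone, 6 and 1 with hybridization control scaling). Epcam fell by 1.13 ± 0.19 (adjusted p = 0.00544), Gata6 by 0.81 ± 0.19 (-0.37 at another probe set) and Cdh1 by 0.79 ± 0.20, and Upk1b rose by 1.53 ± 0.29 (adjusted p = 0.00987). The surface epithelium list did not shift (median -0.44, adjusted p = 0.277), except without AMH replicate 2 (0.00746, against 0.905 without AMH replicate 1). The calls of Gata6 and Cdh1 were lost without control replicate 1 (0.14 and 0.0927) and control replicate 2 (0.131 and 0.213). Across all alternatives these genes and Hba-a3 ran from 0.000991 (Hba-a3) to 0.213 (Cdh1).

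Other cell types that a cultured ovary can hold were mostly not called. Of 22 macrophage and leukocyte markers, Cd68 rose by 1.04 ± 0.21 and C1qb fell by 1.51 ± 0.28 (89.3 to 21.2, below the filter level, and -0.84 with 64 added). Of 17 smooth muscle and pericyte markers, Tpm2 rose by 1.11 ± 0.25 (AMH arrays 295.5 and 524.8, 0.71 without AMH replicate 2 and 1.51 without AMH replicate 1, lost with hybridization control scaling at 0.156, the highest of 0.000483 to 0.156 over its alternatives) and Acta2 and Des fell by 1.19 ± 0.24 and 1.02 ± 0.20. Of 16 endothelial markers, Ecscr rose by 0.88 ± 0.22, a call absent when adjusted over the list alone. Of 9 oviduct and ciliated cell markers, Cdh16 rose by 1.46 ± 0.42 and Tekt1 fell by 1.25 ± 0.20, and 0 of 11 adipocyte markers were called. The control arrays of Cdh16 read 4.3 and 38.1, with a mean of 21.2 below the filter level. Its rise was 2.41 with 1 added in place of 16, and 0.757 without control replicate 1. Adjusted over the list alone, the macrophage list gave 1 rise and 1 fall, smooth muscle 1 and 2, endothelium 0 and 0, oviduct 1 and 1 and adipocytes 0 and 0. With hybridization control scaling no marker of these 5 lists was higher, and 2, 3, 2, 1 and 0 were lower. The list tests gave adjusted p = 0.794 for macrophage, smooth muscle and endothelial markers and 0.882 for oviduct and adipocyte markers, and the adipocyte median (-0.03) and mean (0.16) differed in sign. The macrophage list was lower without AMH replicate 2 (0.00292, against 0.933 without control replicate 1) and the adipocyte list higher without control replicate 2 (0.0125, against 0.968 with median centring). Leaving out control replicate 1 ended the calls of C1qb (0.0677), Acta2 (0.127), Ecscr (0.134), Cdh16 (0.221) and Tekt1 (0.0508). Those of Cd68 (0.0893), Des (0.0995) and Ecscr (0.0543) ended without control replicate 2 and those of Ecscr (0.0503) and Cdh16 (0.0682) without AMH replicate 2, and across all alternatives these 7 genes ran from 0.00148 (Tekt1) to 0.278 (Ecscr). Cdh16 failed in 7 of 14.

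Wnt signalling genes were called about as often as all tested genes (1173 of 10622 higher and 1259 lower). Of 28 measured, Wnt5a, Fzd6 (1.06 ± 0.19), Wnt4 and Fzd1 (0.59 ± 0.16) rose, and Axin2, a target and inhibitor of the pathway (-1.73 ± 0.22, 119.8 to 24.95, adjusted p = 0.00206, and -1.05 with 64 added), Sfrp1, a secreted inhibitor (-1.15 ± 0.18, adjusted p = 0.00466, with -0.55 and -0.08 at other probe sets), and Lrp6 (-0.76 ± 0.21) fell (4 and 3 adjusted over the list alone, 1 and 7 with hybridization control scaling). Of 15 Notch and gap junction genes, Gja4 and Hes1 (0.55 ± 0.16) rose and Heyl (-1.06 ± 0.30, and -0.674 without AMH replicate 2, with 0.32 at another probe set and an adjusted p of 0.349 in their mean) fell (4 and 1 adjusted over the list alone, 0 and 3 with hybridization control scaling). Neither list shifted (adjusted p = 0.981 and 0.452), and the Wnt mean (0.04) and test (down) differed in sign. Without control replicate 1 the adjusted p was 0.187 for Wnt4, 0.163 for Fzd1, 0.307 for Lrp6, 0.194 for Gja4, 0.257 for Hes1 and 0.114 for Heyl. Without control replicate 2 it was 0.242 for Fzd1, 0.0609 for Lrp6, 0.0787 for Gja4, 0.245 for Hes1 and 0.144 for Heyl. Without AMH replicate 1 it was 0.0609 for Wnt5a (log2 fold change 0.82, and 2.68 without AMH replicate 2) and 0.064 for Hes1, and without AMH replicate 2 0.0517 for Lrp6 and 0.0736 for Heyl. The mean over the probe sets of Sfrp1 had an adjusted p of 0.0668, and across all alternatives these genes ran from 0.000108 (Wnt5a) to 0.799 (Hes1).

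**Figure D3:**
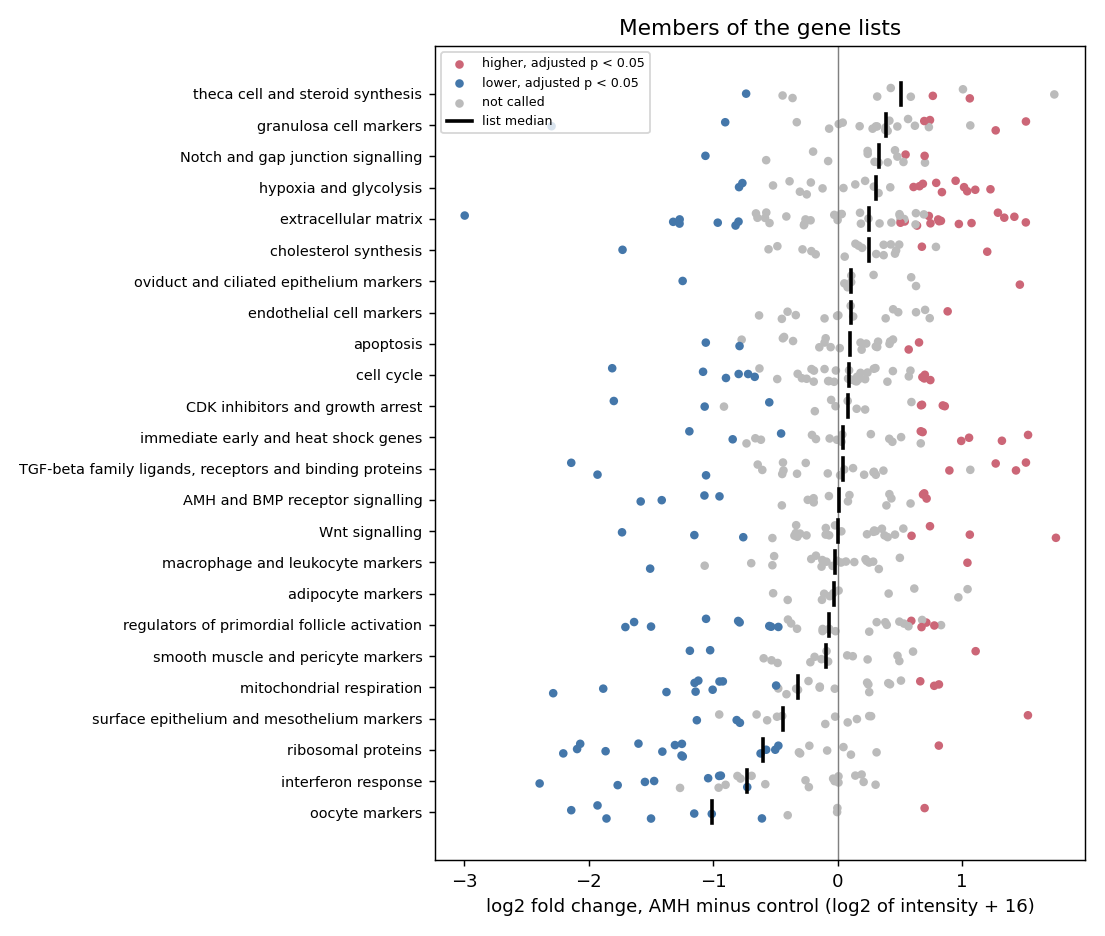
Log2 fold change of each measured member of the 24 tested lists (horizontal axis, AMH minus control, log2 of intensity + 16), 1 point per gene, red for higher and blue for lower at an adjusted p under 0.05, grey for not called, with a black bar at the list median. The medians of the ribosomal protein (-0.60), interferon (-0.73) and oocyte (-1.01) lists lie furthest to the left.

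Of the 24 lists tested, 4 shifted (ribosomal proteins, interferon response, oocyte markers and mitochondrial respiration), all downward, by camera with a preset correlation of 0.01 between genes. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.984, and fry, which asks whether a list's genes move one way on balance, passed 0 lists (lowest adjusted p = 0.142). The estimates ran from -0.062 (oocyte markers) to 0.633 (interferon response). As the run that estimates them has only 2 residual degrees of freedom, it cannot tell whether correlation between genes accounts for a call. The number of lists passing was 2 without AMH replicate 1 and 8 without AMH replicate 2.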

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

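The tests of explanations in this part were chosen after the results were seen, while the list tests, the estimated correlation, fry and quantile normalization were fixed beforehand. Control probe sets outside the comparison differed between the groups. The 3′/5′ ratio of GAPDH was 5.3 times as high (mean 1.22 in control and 6.46 with AMH), that of beta-actin 3.23 times (3.88 and 12.6), and the hybridization controls 1.4 times (995.8 and 1398). The signals behind the ratios were lower with AMH, at 0.151 times the control level for the 5′ and 0.802 times for the 3′ probe set of GAPDH, and 0.0563 and 0.192 times for beta-actin. These values came from 2 arrays per group and the differences were not tested.

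Ribosomal protein genes were lower as a list at the preset correlation (adjusted p = 1.59e-07), a call lost with an estimated correlation (adjusted p = 0.984) and with fry (0.142). A general trend with gene span would place the list within the central 95% of lists matched on span and level, but the median of its 21 members with a span lay at percentile 1.44 of 10000 such lists. Those lists were drawn gene by gene, without correlation between members, so that percentile may be too extreme. Array scaling as the whole cause is argued against by quantile normalization, which moved the list's median from -0.60 to -0.28 and left an adjusted p of 0.000382. Loss of signal along transcripts stays open: probe sets of the same gene differed by over 2 standard errors in 3 of 3 ribosomal protein genes with at least 2 tested probe sets (Rps24, -2.20 and 0.44, Rpl3, -0.23 and 0.70, and Rpl7, -0.30 and 0.89), too few to decide. The second probe sets were also far dimmer in control (8130 and 90.7 for Rps24, 7643 and 194.9 for Rpl3, 5866 and 159.4 for Rpl7). Such pairs compare unlike signals and say little about this explanation. The batch of arrays stays open too, since 0 run strings were shared by both groups. A response of the tissue to AMH cannot be told apart from that batch, so it may account for the fall but remains untested.

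Oocyte markers were lower as a list at the preset correlation (adjusted p = 0.00437), a call lost with an estimated correlation (adjusted p = 0.984) and with fry (0.142). The estimated correlation (-0.062) lay below the preset one, so it was not what ended the call in that run. A lower share of oocyte RNA would lower all markers alike, and 4 of 11 (Gja4, Zp3, Zp2 and Ooep, the last itself called lower) had intervals above the list's median. These intervals hold the spread of replicates only. Probe sets of 1 gene differed with an SD of 0.627, against 0.214 expected from the replicates. The test therefore cannot decide, and a lower share of oocyte RNA stays open. The gene span trend as the whole cause is argued against by a percentile of 0.03 among 10000 matched lists. These were drawn gene by gene, without correlation between members, so the percentile may be too extreme. Loss of signal along transcripts could not be tested, as 0 oocyte markers had 2 or more tested probe sets. An action of AMH on oocyte gene expression may account for the pattern and stays open beside the batch, which is confounded with the groups.

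Probe sets of 1 gene often disagreed. Of 280 genes with 2 or more probe sets called, 99 had calls in opposite directions (median 130 when the directions of the calls were shuffled, 107 to 154 in 1000 shuffles). Replicate noise is argued against, since the SD between probe sets of a gene was 2.93 times that expected from the replicates. Loss of signal along transcripts may contribute and stays open: the 5′ probe set fell further than the 3′ one for 2 of 3 control genes (GAPDH and beta-actin; hexokinase, -0.45 at the 5′ and -0.59 at the 3′ end, read 8.85 and 2.1 at the 5′ end and 35.1 and 18 at the 3′ end, near the floor), but probe positions within other transcripts were not at hand. Different transcripts of a gene under AMH remain an untested biological explanation.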

How the results depend on the processing

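Scaling to the hybridization controls and removal of a gene span trend were chosen after seeing the data; the other alternatives were planned. All 12 largest falls kept their direction and call wherever tested, and of 100 named genes that were called, 97 kept the call with median centring, 96 with the span trend removed, 83 without the eBayes trend, 82 with no filter, 82 with the mean of a gene's probe sets and 70 of 99 with hybridization control scaling. Without control replicate 1 the call was kept by 60, without control replicate 2 by 71, without AMH replicate 1 by 95 and without AMH replicate 2 by 91. No alternative separated AMH from the batch of arrays or from the difference in 3′/5′ ratio, so a kept call does not exclude either. Where a call or direction was lost, the cause was not tested, beyond the fewer arrays or probe sets that a setting itself brings. With 1 array left in a group, that array was assumed to vary like the other group. Brightness limits genes near the floor, such as Cyp19a1, Kit and Rpl28. The replicate numbers share only a number: the correlation of the differences between replicates was -0.001, and the replicate block moved the changed probe sets to 3566 (1350 higher and 2216 lower) and the lists to 3.

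Rises numbered 1010 with no filter, 989 without the eBayes trend, 2593 at an adjusted p under 0.10 and 145 with hybridization control scaling, where falls numbered 4960. Lists passing numbered 2 with the lowest 60% left out, 0 with an estimated correlation and 0 with fry. Leaving out single arrays gave 1381 to 5131 changed probe sets, 334 to 2245 higher, 1047 to 2886 lower and 2 to 8 lists. The list of mitochondrial respiration had an adjusted p of 0.111 with pseudocount 1, 0.113 with the lowest 60% left out, 0.0716 without the eBayes trend and 0.0608 with the replicate block.

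Log2 fold changes that turned sign were, with quantile normalization, Id2 0.138, Irf7 -0.032, Rpl3 0.011, Rpl7 0.031, Tgfb1 0.01, Zp2 0.102 and Zp3 0.114. With median centring they were Id2 0.027, Tgfb1 0.018, Zp2 0.093 and Zp3 0.095, and with pseudocount 1 Irf7 -0.005. The mean of a gene's probe sets gave Acvr1 -0.599, Ifit2 -0.045, Igf1 -0.046, Mcl1 -0.08, Rpl3 0.237, Rpl7 0.296, Smad1 -0.521, Smurf2 -0.015, Uqcrc2 -0.321 and Wt1 -0.425. Hybridization control scaling gave Acvr1 -0.025, Amh -0.026, Dynlrb2 -0.225, Foxl2 -0.084, Ifih1 -0.118, Ifit2 -0.131, Irf7 -0.456, Kitlg -0.066, Rpl22 -0.17, Smad1 -0.373 and Wt1 -0.223. With the span trend removed they were Id2 0.21, Zp2 0.081 and Zp3 0.142.

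Leaving out single arrays gave ranges across 0 for Bmpr1a (-0.411 to 0.027), Cidea (-1.114 to 0.078), Cyp19a1 (-0.151 to 0.505), Dgat2 (-0.246 to 0.031), Dynlrb2 (-1.026 to 1.246), Id2 (-0.330 to 0.191), Ifit2 (-0.259 to 0.869), Irf7 (-1.141 to 1.156), Isg15 (-2.437 to 0.525), Mx1 (-2.154 to 0.595), Zp2 (-0.232 to 0.224) and Zp3 (-0.231 to 0.227).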

Other observations

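The gene families and probe sets in this part were all chosen after the data were seen. Their adjusted p-values are therefore descriptive and are not independent tests. Proteasome genes were lower with AMH: of 36 measured, 18 fell and 2 rose (median -0.43, camera adjusted p = 0.000902 over 14 families), among them Psmb9 (-1.77 ± 0.28), Psmb1 (-1.72 ± 0.14) and Psmb10 (-1.69 ± 0.29), while Psmd14 rose by 0.86 ± 0.14 (-0.35 and -0.08 at other probe sets) and Psmd5 by 0.58 ± 0.15. The family kept its direction and call in every scaling, though median centring and hybridization control scaling move all genes of an array nearly alike. It kept its direction with any 1 array left out, but its call was lost with an estimated correlation (adjusted p = 0.577). The mean GAPDH 3′/5′ ratio on these arrays was 1.22 in control and 6.46 with AMH. Of 9 ADAMTS proteases, which remodel the matrix, 4 rose and 0 fell (median 0.65, 0.23 with hybridization control scaling, adjusted p = 0.0264, and 0.577 with an estimated correlation), with Adamts4 at 1.45 ± 0.20, Adamts1 at 1.42 ± 0.24 and Adamts9 at 1.04 ± 0.21 (0.15 at another probe set). Of 16 ATP synthase genes 8 fell and 2 rose (median -0.49, adjusted p = 0.0264, 0.577 with an estimated correlation and 0.15 without AMH replicate 1), led by Atp5mg (-2.63 ± 0.18) and Atp5pd (-1.93 ± 0.14). Among 11 cathepsins, Ctsc, Ctsa (1.01 ± 0.17) and Ctsh (0.94 ± 0.16) rose and Ctsd (-1.34 ± 0.16) and Ctsz (-1.03 ± 0.21) fell, and the family did not shift (adjusted p = 0.383). Leaving out control replicate 1 ended the calls of Psmd14 (0.0595), Psmd5 (0.269), Ctsh (0.0504) and Ctsz (0.0509), and leaving out control replicate 2 those of Psmd5 (0.131) and Ctsz (0.0607).

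Of the genes with at least 2 tested probe sets, 98 had all of them called in 1 direction, 22 higher and 76 lower. Both probe sets of Hdac1, a histone deacetylase, fell (-2.27 and -2.63), as did those of Sparc (-1.39 and -1.32) and Cenpv (-1.43 and -1.68). Those of Aspn, a small matrix proteoglycan that binds TGF-beta, rose (1.07 and 1.19), as did those of Spaca6 (1.03 and 1.02). Without control replicate 1 the brighter probe set of Aspn (0.087) and that of Spaca6 (0.0613) were not called. The call of Aspn was lost in 5 of 15 alternatives, among them median centring (0.0555), no filter (0.085), eBayes without trend (0.0792) and hybridization control scaling (0.26, against 0.000217 at the lowest), and its log2 fold change was 0.51 without AMH replicate 2 and 1.64 without AMH replicate 1.

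Genes with a short span in the genome fell more often than long ones. In the tenth of genes with the shortest span 22.5% were lower and 7.74% higher, against 6.89% lower and 11.8% higher in the tenth with the longest (Spearman rho of span with log2 fold change 0.126 over 10584 genes, which are not independent replicates).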
